A study of Mus musculus with 6 samples.

How the data were processed

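Small RNA from mouse serum was sequenced in 6 libraries after sciatic nerve allografting, a transplant of donor nerve into a gap in a genetically different recipient. Serum was taken at days 3, 7 and 14 from animals given FK506 (tacrolimus, a calcineurin inhibitor that blocks T cell activation) at 1 mg/kg per day, and from animals given none. Each combination of treatment and day is 1 library. The labels state 3 animals per group and day, but whether a library holds RNA of 1 animal or of a pool is not given in the sources used here.

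The deposited values are read counts per mature miRNA, with no normalization. Per the labels' protocols, short RNA was size-selected on gels, ligated to linkers and made into barcoded cDNA, and the libraries were sequenced in a shared lane. That lane held more barcoded libraries than the 6 analysed here. Also per the labels' protocols, linkers were trimmed and reads were matched to mouse precursor and mature miRNAs of miRBase with Bowtie and BLAST. Bowtie is also named in the submitters' processing notes. Tool versions, the genome build, the mismatch setting and the handling of reads that match several entries are not given in the sources used here. A read matching several miRNAs can therefore be counted at each of them, which raises the totals and leaves near-identical family members uncertain. The labels name C57BL/6 as the recipient strain in one place and Balb/c in another, so the strain combination is not stated further here.

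Library totals ran from 4897727 to 5806228 counts over 1281 entries, of which 507 had a read in any library. The 2 entries miR-486-5p and miR-3107-5p took 93.8% to 98.0% of each total, so the depth behind all other miRNAs was 103058 to 359061 reads per library. Intervals are exact 95% binomial intervals of the ratio of 2 counts and, like the floors, cover counting error only, because reads carry no molecular identifiers.

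Effective library sizes were computed with TMM in edgeR 4.0.16 under R 4.3.3, over the 153 miRNAs kept by filterByExpr with treatment as the group and a minimum count of 10. With 1 library per group, FK506 and untreated were compared at each day, and later days with day 3 within each arm, by the log2 ratio of scaled counts with a prior count of 2. A miRNA passed the size rule with a log2 ratio of at least 1 or at most -1 and at least 50 reads in 1 of the 2 libraries. These single-library comparisons have no replicate check and no p-value. Folds printed with an interval are ratios of scaled counts without the prior count. A fold against a count of 0 was computed against a floor of 3 reads in that library and is a lower bound.

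Across days, all 6 libraries were fitted with edgeR's quasi-likelihood test, with day and treatment as terms and Benjamini-Hochberg adjustment at 0.05. The spread in that fit is the treatment-by-day difference of single libraries, on 2 residual degrees of freedom. Some of that difference may be technical. The test moderates the spread of each miRNA toward that of all miRNAs fitted. Its p-values therefore also rest on this pooled spread, not on the 2 degrees of freedom alone. DESeq2 1.42.0 and limma 3.58.1 were alternatives. The fit was tested on simulated counts with known changes. At the dispersion of these libraries it recovered 19.1% of 4-fold, 66.7% of 8-fold and 86.7% of 16-fold FK506 changes over a median of 147 miRNAs, and 2.67% of its calls were false. The simulated counts had a common dispersion for all miRNAs, the same change at every day and no library that stood apart. These rates may therefore not hold for the real libraries.

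The groupings were 14 miRNA lists: erythroid, myeloid and platelet, lymphocyte, immune activation, liver, skeletal and cardiac muscle, neuron and glia, pancreas and gut epithelium, let-7 family, miR-17 to miR-92 clusters, miR-30 family, Dlk1-Dio3 imprinted cluster, Sfmbt2 cluster, and entries resembling fragments of other RNAs. A member counted as measured with at least 50 reads in any library, and a list needed 3 measured members. The median log2 ratio of a list is given with its percentile among 10000 random lists matched on mean level in 5 bins, as a description of these libraries. Across days the lists were tested with camera at its preset correlation, camera with an estimated correlation, and fry. Red cell lysis was described by the ratio of miR-451a to miR-23a-3p.

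The groups, tests, lists, size rule, most alternatives and the rule for named miRNAs were fixed before the data were examined. That rule takes, per day, the 10 highest and 10 lowest miRNAs past the size rule. For the fit across days it takes those past the threshold and, as fewer than 10 passed, the 10 with the largest smallest absolute log2 ratio among those of 1 direction at all 3 days. Within an arm it takes the 6 highest and 6 lowest, and it adds the 10 most abundant miRNAs and the highest-level members of each list. The text summarises part of each set. A miRNA named outside the rule is said to have been chosen after its values were seen. Alternatives covered the scaling, read floor, prior count, filter, test, model terms and left-out days, and a few more were added after seeing the data. Positions of miRNA genes come from GENCODE M21 on GRCm38.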

Results

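Serum miRNAs were counted after sciatic nerve allografting in 6 libraries, 1 per treatment and day: FK506 at days 3, 7 and 14, and no FK506 at the same days. The total was 4992998, 5068245 and 5806228 counts in the FK506 libraries at days 3, 7 and 14, and 5137675, 4897727 and 5357177 in the untreated libraries. Because each group held 1 library, differences at a single day have no replicate check, and their intervals are 95% counting intervals.

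The erythroid miRNA miR-486-5p dominated every library, with 2302676 to 2727053 reads. The entry miR-3107-5p carried 99.5% to 99.8% as many reads as miR-486-5p. Their genes lie on opposite strands of chromosome 8 (GRCm38), Mir486 at 23142555 to 23142682 on the plus strand and Mir3107 at 23142573 to 23142662 on the minus strand, in an intron of the protein-coding gene Ank1. Their precursors share a stretch of 22 nt in the same orientation, so reads of the 2 entries cannot be separated. After this pair the most abundant entries by mean share were miR-181a-5p, miR-92a-3p, miR-25-3p, miR-10b-5p, miR-191-5p, let-7f-5p, miR-30a-5p and miR-22-3p. The reads outside the pair numbered 104574, 103058 and 359061 in FK506 at days 3, 7 and 14, and 160163, 298117 and 158423 in untreated serum. Precision still differs by miRNA: miR-150-5p had 426 reads in the untreated day 7 library against 948 and 622 at untreated days 3 and 14, and miR-23a-3p had 12 against 63 and 55. The ratio of miR-451a to miR-23a-3p, a measure of red cell lysis, was 23.5, 13.7 and 26.4 in FK506 at days 3, 7 and 14, and 21.0, 43.6 (interval 24.7 to 84.9) and 14.5 in untreated serum.

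**Figure D1:**
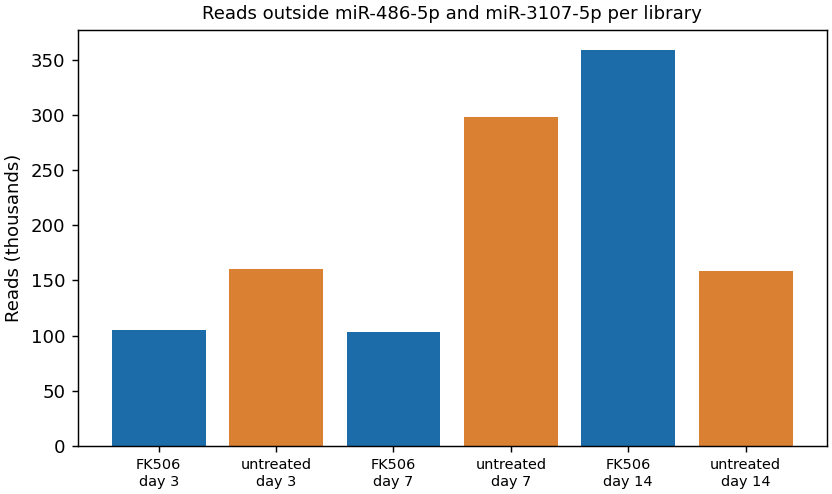
Reads outside miR-486-5p and miR-3107-5p (bars from 0) in each library, with FK506 in blue and untreated in orange. The FK506 day 14 library (359061 reads) and the untreated day 7 library (298117 reads) stand above the others.

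The comparison of FK506 with no FK506 across the 3 days asked which circulating miRNAs went with immunosuppression of the graft recipient. The lymphocyte miRNA miR-150-5p was higher in FK506 at every day, by 9.13-fold at day 3 (interval 8.52 to 9.79), 12.7-fold at day 7 (11.5 to 14.0) and 5.36-fold at day 14 (4.94 to 5.82). Its gene is annotated outside any other gene on chromosome 7, from 45121757 to 45121821. Other miRNAs at least 2-fold higher at all 3 days were miR-215-5p, an intestinal and p53-responsive miRNA, with log2 ratios of 1.57, 1.66 and 1.66, miR-434-3p of the imprinted Dlk1-Dio3 cluster, and miR-199a-3p with its identically counted copy miR-199b-3p. The let-7 members let-7a-5p, let-7f-5p and let-7i-5p were at least 2-fold lower at all 3 days. For let-7a-5p, a differentiation-associated miRNA, the log2 ratios were -1.28, -3.43 and -2.50.

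With TMM scaling, 5 miRNAs were higher and 3 lower at every day among 93 compared, and none when FK506 and untreated were exchanged at any 1 day. Scaling to the library total left 1 higher and 1 lower, miR-150-5p and let-7a-5p. Under that scaling an exchange at day 14 also gives miRNAs of 1 direction. Among these are miR-30a-5p, at -1.85, -1.37 and 1.37 before the exchange, and miR-146b-5p, at -2.22, -2.68 and 1.96. The contrast with exchanged days therefore depends on the scaling. In the fit across days with edgeR, 0 of 153 miRNAs passed an adjusted p of 0.05, while 17 lay under an unadjusted 0.05, 8 higher and 9 lower. That count was 9 scaled to the library total, 4 without day 3 and 32 with no day term. DESeq2 called 5 (miR-150-5p, miR-378c and miR-296-5p higher, let-7a-5p and let-7f-5p lower) and limma called 1, miR-150-5p; miR-378c and miR-296-5p were singled out after their values were seen. In edgeR miR-150-5p had a log2 change of 3.09 ± 0.675 (SE), with an adjusted p of 0.0776, and was higher in 3 of 3 pairs; over 13 alternatives its adjusted p ran from 2.28e-05 to 0.940. The adjusted p was 0.185 for let-7a-5p (-2.41 ± 0.712), 0.284 for let-7f-5p and 0.314 for miR-215-5p. The next miRNAs of 1 direction at all 3 days were miR-142-5p, a blood cell miRNA, at 1.00, 1.59 and 1.22, and miR-181a-5p at -1.17, -4.83 and -0.98 (0.35 at day 14 scaled to the library total).

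**Figure D2:**
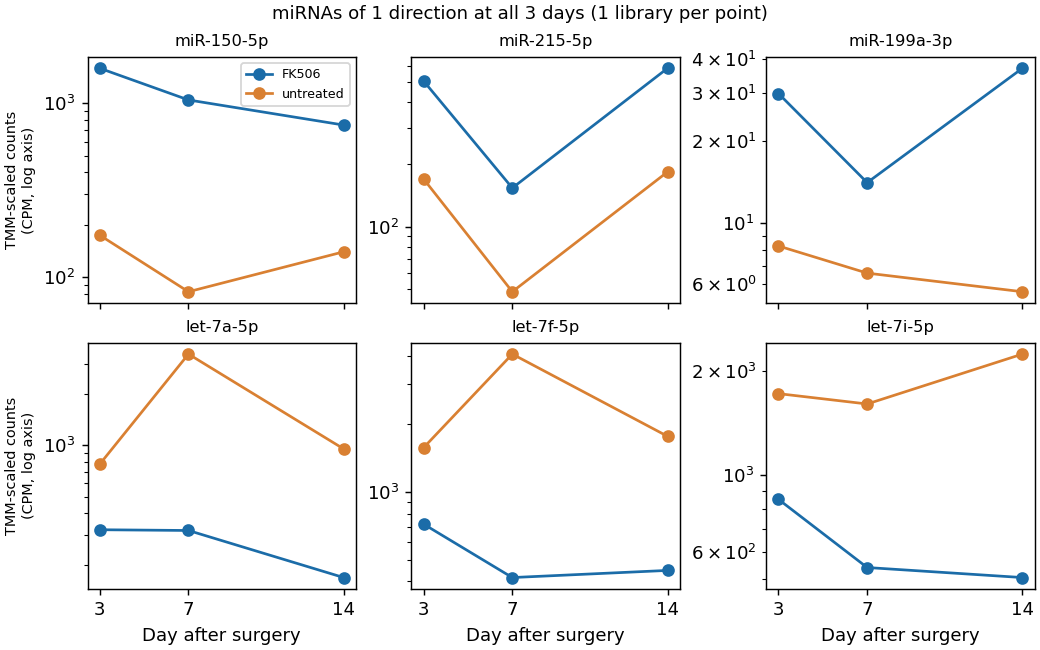
TMM-scaled counts (CPM, log axis) against the day after surgery for 6 miRNAs of 1 direction at all 3 days, 1 library per point, FK506 in blue and untreated in orange. For miR-150-5p the FK506 values are 1590, 1045 and 749 and the untreated values 174, 82.4 and 140.

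Of the lists, the let-7 family was lower in FK506 across days with camera at its preset correlation (adjusted p 0.0044, 7 of 9 members negative, median log2 change -1.50). The adjusted p was 0.946 with an estimated correlation and 0.435 with fry, and 0.0578 without the untreated day 7 library. Of the 9 members 0 passed over all miRNAs, and 2 passed adjusted over the list alone. Myeloid and platelet miRNAs had positive changes in 8 of 8 members (median 0.82), with an adjusted p of 0.0631 at the preset correlation and 0.946 with an estimated correlation. In the lymphocyte list 1 member, miR-150-5p, passed adjusted over the list alone, while 7 of 9 members had negative values. The erythroid, immune activation, liver, miR-17 to miR-92, miR-30 and Dlk1-Dio3 lists did not pass the preset test, with adjusted p-values of 0.316 or more for these and the lymphocyte list. The other lists, among them neuron and glia and pancreas and gut, had fewer than 3 members in the fit of all 6 libraries. They were not tested in it.

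At day 3, FK506 serum had more of the lymphocyte miRNA miR-150-5p, of miR-107-3p (4.31-fold, 3.58 to 5.23), miR-205-5p, an epithelial miRNA (3.50-fold), miR-328-3p (3.17-fold) and let-7b-5p (2.84-fold). It had less of miR-146b-5p, a feedback regulator of inflammatory signalling (3.13-fold lower, 2.41 to 4.13), miR-15b-5p (3.16-fold lower), miR-30a-5p (2.38-fold lower) and miR-181a-5p (2.25-fold lower). By list, 3 of 9 measured let-7 members were lower and 1 was higher (median -0.63, percentile 0.68), and 2 of 7 miR-30 family members were lower (median -0.70, percentile 1.02). Myeloid and platelet miRNAs had 2 of 8 higher (median 0.95, percentile 96.3), with miR-126-5p at 1.07 and miR-199a-3p at 1.81. Lymphocyte miRNAs had 1 higher and 1 lower of 8 (median -0.50, percentile 2.93). Of 99 miRNAs compared, 21 were higher and 11 lower. Scaled to the library total, which moved the median of all by -0.58, 7 were higher and 30 lower, and with median-of-ratios factors 12 were higher.

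At day 7 the widest differences were in miRNAs of the nervous system, most of which were near 0 in FK506 serum and present in the untreated library. The neuronal miRNA miR-9-5p had 7683 reads without FK506 and 0 with it, at least 1862-fold lower against the floor of 3 reads. Also at 0 with FK506 were miR-124-3p, the main neuronal miRNA (182 reads untreated), and the oligodendrocyte miRNAs miR-338-3p (347 reads) and miR-219-2-3p (467 reads). Summed over the 19 neuron and glia list members matched by name, which leaves out miR-219-2-3p, the log2 ratio was -4.85. The 50-read floor selects for this difference: of the 10 measured members, all lower in FK506 (median -5.95, or -5.10 with zero counts at their bound), 8 reached it only in the untreated day 7 library. With the floor applied to the other 5 libraries, 2 members were measured and 2 were lower. Of the 9 members below the floor, 5 had more reads untreated and 4 had 0 in both libraries of the pair. In the Dlk1-Dio3 list 9 of 11 measured members were lower (median -4.87, or -3.93 at the bound), with miR-381-3p at 1 against 611 reads and miR-411-5p at 5 against 674. Of these 11, 7 were measured only through that library, and with the floor applied to the others 2 were lower and 2 higher by log2 ratio alone. Of the 2 higher, miR-541-5p had 18 reads with FK506 and 9 without, short of the 50 reads of the size rule. Lower in FK506 too were let-7e-5p (161-fold, 102 to 272), miR-204-5p (67.1-fold, 43.8 to 109) and miR-181a-5p, with 94740 reads untreated. The genes of miR-9 lie on chromosomes 3 (88215598 to 88215686), 13 (83738814 to 83738885) and 7 (79505264 to 79505353), each within a long noncoding RNA gene.

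Most of these nervous-system reads lay in the untreated day 7 library. The other 5 libraries together held 1 read of miR-9-5p and 0 of miR-124-3p, but 1088 of miR-128-3p against 1348 in that library. Across 153 miRNAs, which are not independent replicates, its log2 levels correlated with those of the other libraries at 0.82 to 0.87, against 0.93 to 0.98 among the others. Higher in FK506 at day 7 were miR-150-5p, miR-10b-5p (4.88-fold), the muscle miRNA miR-133a-3p (4.76-fold), miR-142-5p (3.02-fold) and miR-10a-5p (2.86-fold). Of the 8 lymphocyte-list members 5 were lower (median -1.62, percentile 2.94), led by miR-181a-5p, miR-181b-5p and miR-26a-5p, which are also made outside lymphocytes. The let-7 list had 5 of 9 lower (median -1.57, percentile 2.47) and the myeloid and platelet list 3 of 8 higher (median 0.61). Without let-7e-5p, measured only through the untreated day 7 library, 4 of 8 let-7 members were lower (median -1.27). Of 129 miRNAs compared, 25 were higher and 60 lower, or 24 and 42 without the neuron, glia and Dlk1-Dio3 lists. Scaling to the library total moved the median by -0.51 and gave 9 higher, and leaving out the top 3 miRNAs before scaling moved it by 1.27 and gave 50 higher.

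**Figure D3:**
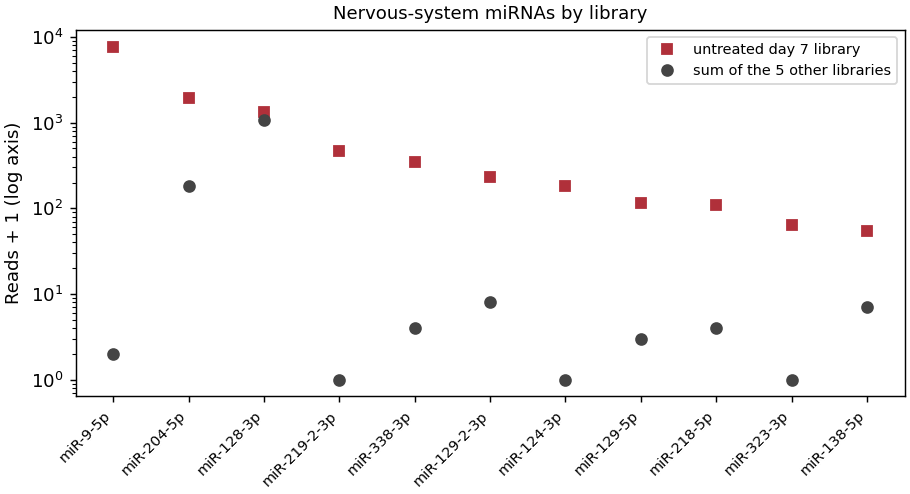
Reads plus 1 (log axis) of the 10 measured neuron and glia miRNAs and miR-219-2-3p, in the untreated day 7 library (red squares) and summed over the other libraries (grey circles). For miR-9-5p the values before adding 1 are 7683 and 1 reads.

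At day 14, 6 of 8 measured members of the myeloid and platelet list were higher in FK506 serum (median 1.54). Of the 8, 4 reached the floor only in the FK506 day 14 library, and without these 3 of 4 were higher (median 1.66). The most abundant member, miR-191-5p, was at -0.77 (0.55 scaled to the library total), and the summed list had 1831 TMM-scaled CPM in FK506 against 2308 untreated. Among the higher members were miR-126-5p, an endothelial and platelet miRNA (4.29-fold, 3.68 to 5.03), miR-142-3p (5.95-fold, 2.64 to 16.6) and miR-199a-3p (6.58-fold, 4.40 to 10.3). Higher as well were miR-574-3p (7.79-fold, 5.26 to 12.0), miR-143-3p, a smooth muscle miRNA (3.74-fold), and miR-378c (10.1-fold, 3.84 to 37.8). Its relative miR-378d had 99 reads against 0, at least 12.1-fold higher, and the epithelial miR-429-3p had 54 against 0, at least 6.63-fold higher. The hepatocyte miRNA miR-122-5p had 1 read with FK506 and 60 without, a ratio of 163 with a counting interval of 28.2 to 6545. Of 9 let-7 members 5 were lower (median -1.08, percentile 0.46), with let-7a-5p 5.67-fold, let-7d-5p 4.48-fold and let-7i-5p 4.41-fold lower, and miR-423-5p was 4.27-fold lower.

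Of 130 miRNAs compared at day 14, 27 were higher and 20 lower. Scaling to the library total moved the median by 1.31 and gave 84 higher and 3 lower, and the medians of all 11 lists were then above 0, with let-7 at 0.22. The effective size of the FK506 day 14 library was 2.08 times its filtered total, against 0.697 to 1.06 in the others.

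The erythroid list had 2 higher and 1 lower of 10 at day 3, 3 and 0 at day 7, and 0 and 4 at day 14 (medians -0.07, 0.58 and -0.54), with miR-486-5p at 0.62, 0.57 and -1.38. Scaled to the library total the day 14 medians were 0.76 for this list, 0.85 for the lymphocyte list and 0.98 for the liver list, and miR-486-5p was at -0.05. The lymphocyte list had 1 of 8 higher at day 14 (median -0.44). Immune activation miRNAs had medians of -0.02, -1.20 and -0.00, with 4 of 8 lower at day 7, among them miR-146b-5p and miR-125b-5p; the day 7 median was -0.62 without 1 member measured only in the untreated day 7 library, and 0.06 with the top 3 miRNAs left out before scaling. Liver miRNAs had medians of 0.51, 0.51 and -0.34 over 4 members (-0.08 at day 3 scaled to the library total, and 0.15 at day 14 without miR-122-5p, measured only in untreated day 14), and pancreas and gut miRNAs 0.88, 0.72 and 1.31 over 4, including miR-215-5p and, with log2 ratios of 1.01, 0.67 and -0.49, miR-375-3p. In the pancreas and gut list 2 of the 4, miR-141-3p and miR-429-3p, reached the floor only in the FK506 day 14 library. For the miR-17 to miR-92 clusters the medians were 0.20, 0.70 and -0.13 over 6 members, including miR-92a-3p and miR-25-3p (-0.39 at day 3 and 1.20 at day 14 scaled to the library total, and -0.57 at day 14 without 1 member measured only in FK506 day 14). The miR-30 family had medians of -0.29 at day 7 (0.97 with the top 3 left out) and -0.03 at day 14, and the Dlk1-Dio3 list 0.00 at day 3 and 0.64 at day 14. Neuron and glia miRNAs had medians of 0.00 at day 3 and 0.56 at day 14, or 0.00 at both days with zero counts at their bound, which 7 and 8 of 10 members had. The muscle list had 1 measured member, and the Sfmbt2 and fragment lists had 0, so no median was formed.

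**Figure D4:**
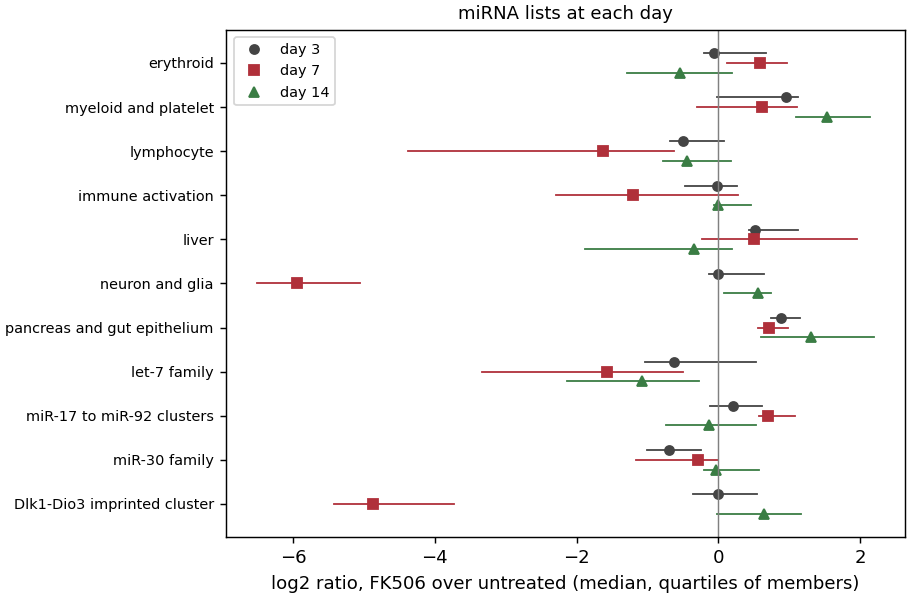
Median log2 ratio of FK506 over untreated (points) with the quartiles of the members (lines) for 11 miRNA lists at day 3 (circles), day 7 (squares) and day 14 (triangles). The neuron and glia list at day 7 has the lowest median, -5.95, over 10 members of which 8 were measured only through the untreated library of that day.

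The time course within each arm asked how serum miRNAs moved after day 3. In FK506 at day 7, 3 miRNAs were higher and 6 lower of 93 than at day 3; miR-574-3p was 3.70-fold higher (2.19 to 6.60), and miR-215-5p was 3.28-fold and the inflammation-linked miR-21a-5p 2.13-fold lower. Leaving out the top 3 before scaling gave 3 lower. By day 14 in FK506, 13 were higher and 21 lower of 128, with miR-574-3p (8.80-fold), miR-126-3p (3.24-fold), miR-30a-5p (3.03-fold) and miR-30e-5p (2.97-fold) higher and miR-423-5p (4.49-fold) and miR-92b-3p (3.88-fold) lower. Scaled to the total, 92 were higher and 0 lower. In untreated serum at day 7, 61 were higher and 18 lower of 128, led by miR-9-5p and by let-7e-5p (234-fold, 148 to 394), while miR-10b-5p was 8.77-fold and miR-10a-5p 5.80-fold lower. Leaving out the top 3 before scaling gave 49 lower. By day 14 in untreated serum, 11 were higher and 7 lower of 102. The liver miRNAs miR-122-5p (14.7-fold, 5.96 to 46.9) and miR-192-5p (4.14-fold) were higher, and the immune-regulated miR-146a-5p (2.88-fold), miR-146b-5p (3.36-fold) and miR-125b-5p (3.56-fold) were lower. Scaled to the total, 4 were higher and 12 lower, and 5 were higher with median-of-ratios factors or with the top 3 left out.

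Across arms, edgeR called 0 of 153 miRNAs for day 7 against day 3, 0 for day 14 against day 3 and 0 for day 14 against day 7, with 7, 0 and 11 under an unadjusted 0.05, or 2, 3 and 6 without the untreated day 7 library and 1, 1 and 5 scaled to the library total. DESeq2 called 1, 0 and 2, namely miR-204-5p higher at day 7 and, for day 14 against day 7, miR-204-5p and miR-92b-3p lower; limma called 0 in each. The arms differ in these miRNAs: at days 3, 7 and 14 the scaled counts (CPM) of miR-204-5p were 7.17, 375 and 2.70 in untreated serum and 4.6, 5.6 and 7.7 in FK506. Those of miR-92b-3p were 20.0, 513 and 21.8 in untreated serum and 46.6, 46.3 and 12.0 in FK506. The liver list was higher at day 14 than at day 7 with camera at its preset correlation (adjusted p 0.0041), but the adjusted p was 0.671 with an estimated correlation and 0.110 without the untreated day 7 library.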

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

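The tests of technical explanations for the 3 patterns below, and the count of splits within days, were chosen after the results were seen. The count over all 10 splits, the level-matched percentiles and the medians scaled to the library total or by median-of-ratios factors were planned.

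Among the named miRNAs, 5 had FK506 to untreated ratios past the size rule in opposite directions at different days with TMM scaling. The difference between days was not tested. For all but miR-423-5p, 1 of the 2 directions comes from day 7, where the untreated library stood apart. At days 3, 7 and 14 the untreated libraries had 39, 1939 and 12 reads of miR-204-5p and 1047, 6608 and 597 of miR-143-3p. They had 109, 2651 and 97 of miR-92b-3p, and 96, 1348 and 109 of miR-128-3p. The log2 ratio of miR-204-5p was -5.98 at day 7 and 1.40 at day 14. For miR-143-3p it was -2.51 at day 7 and 1.90 at day 14. For miR-423-5p it was 1.02 at day 3 and -2.09 at day 14, but 0.41 and -0.77 scaled to the library total, short of the size rule. At days 3 and 7 it was 1.20 and -3.46 for miR-92b-3p, and 1.21 and -1.79 for miR-128-3p. For miR-128-3p it was 0.62 at day 3 scaled to the library total, and -0.53 at day 7 with the top 3 miRNAs left out before scaling. Scaling to the library total moved the median of all at day 3 by -0.58. The day 3 value of miR-92b-3p then falls short of the rule too, with 162 reads of 4992998 in FK506 against 109 of 5137675 untreated.

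Nervous-system miRNAs stood out in the untreated day 7 library. Scaling was argued against, since the log2 ratio of the summed reads of all 19 neuron and glia miRNAs in the data was -3.58 or lower at day 7 under all 4 scalings. Carry-over from the other 5 libraries was argued against as well, because the untreated day 7 library held 90.4% of those reads. Nervous tissue RNA mixed into that library, carry-over from a library not analysed here, and release from nervous tissue of the untreated recipient may each remain. They cannot be told apart with 1 library in the group. Libraries outside this series shared the lane, and what they held is not given in the sources used here. In that library 4.09% of the reads outside miR-486-5p and miR-3107-5p fell on those 19 members. More than these members set it apart: miR-181a-5p, not on that list, took 31.8% of such reads there, against 2.10% to 4.98% in the other libraries. Whether miR-181a-5p has the same source was not tested.

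For miR-150-5p, scaling was argued against by log2 ratios of 2.42 or more at all 3 days under 4 scalings. Red cell lysis cannot be decided from these values. The log2 of the lysis ratio in FK506 over untreated was -1.67 at day 7 and 0.87 at day 14, both beyond counting error. The day 7 ratio rests on 12 reads of miR-23a-3p in the untreated library. Its numerator miR-451a alone was at -0.13, 1.01 and 0.89 at days 3, 7 and 14, while miR-150-5p was higher at all 3 days. A general release of lymphocyte RNA may remain open. The other 7 list members had a median of -0.56 or lower at each day with TMM scaling, but tissues other than lymphocytes also make them. Scaled to the library total, the day 14 median of all 8 measured members, miR-150-5p among them, was 0.85. The sign at that day therefore depends on the scaling. An effect of FK506 on lymphocytes or their release of this miRNA was not tested beyond 1 library per group.

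The let-7 family had negative medians at each day and lay low among level-matched lists, a rank that 1 factor per library cannot move. At day 14 the sign may come from scaling, since the median was 0.22 scaled to the library total, and at days 3 and 7 scaling cannot be told apart, with medians of -0.30 or lower under 4 scalings but members on both sides of 0. The log2 ratio of the family's summed share was -0.57 or lower at all 3 days, with counting intervals below 0. It cannot decide whether reads moved between near-identical members, because a read counted at several members can enter the sum more than once. At days 3 and 14, whose ratios do not use the untreated day 7 library, the percentiles were 0.68 or lower. That library still entered the choice of members: let-7e-5p reached the floor only there, and was at -1.03 at day 3 and 0.46 at day 14. The rank without let-7e-5p was not computed, so how far the low rank rests on that library cannot be told. These percentiles only describe the libraries, as let-7 members vary together (estimated correlation 0.566 in the fit across days). Without the untreated day 7 library the family did not pass with camera at its preset correlation. An effect of FK506 stays open, as do differences between single animals or pools, which may be as large.

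With day kept as a term, 3 of the 10 splits of the 6 libraries into 3 and 3, the real split among them, gave at least as many miRNAs under an unadjusted 0.05 as the real split. The real split gave 17 against a highest other value of 26. With 10 splits no share under 0.05 can be had. The 2 splits with 26 make the same comparison with sides exchanged, that of the pair of day 7 alone, in which the untreated library stands apart. Day pairs the libraries: the 4 splits that part FK506 from untreated, or exchange them, within every day gave 17 (the real split), 5, 1 and 1, and the other 6 put both libraries of a day on 1 side. With 4 splits no share under 0.05 can be had either.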

How the results depend on the processing

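The alternatives that left out miR-3107 entries, single libraries, day 7 from the 3-day count, or the nervous-system lists, list members measured without single libraries, and list medians with the top 3 miRNAs left out, were chosen after the data were seen. Other scalings, other prior counts and leaving out miR-3107 entries gave 629 recomputed log2 ratios of the highest and lowest miRNAs past the size rule at each day or within arms. All kept their sign, 506 of them within the counting interval. Among list members, abundant and across-day miRNAs, 42 of 393 values recomputed under the other scalings turned sign. Of the 180 recomputed from values past the size rule 1 did so, miR-92a-3p at day 14 (0.298 scaled to the library total). Of 231 list medians recomputed under 3 other scalings 40 turned sign, 19 of them scaled to the library total: 2 of 39 from medians past the size rule and 38 of 192 from smaller ones. The 2 are as follows. The let-7 median at day 14 was 0.22 scaled to the library total, and the immune activation median at day 7 was 0.062 with the top 3 miRNAs left out before scaling. Across days miR-150-5p was higher in all 13 alternatives (log2 2.78 to 3.34) and past the threshold in 6, with adjusted p-values from 2.28e-05 to 0.940. The reads outside the dominant pair numbered 103058 to 359061 per library, and the effect of depth was not tested.

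Counts of miRNAs past the size rule moved as follows, and the cause was not tested beyond the way each setting is built. Scaled to the library total, FK506 against untreated had 7 higher and 30 lower at day 3, 9 higher at day 7, and 84 higher and 3 lower at day 14. Day 14 against day 3 then had 92 higher and 0 lower in FK506, and 4 higher and 12 lower in untreated, and the counts of 1 direction at all 3 days were 1 higher and 1 lower. With median-of-ratios factors, 12 were higher at day 3 in FK506, and 5 were higher at day 14 against day 3 in untreated. With a floor of 10 reads, which admits more miRNAs, the counts higher and lower were 32 and 18 at day 3, 46 and 97 at day 7, and 56 and 34 at day 14. Within arms they were 11 higher for day 7 and 35 higher for day 14 in FK506, 96 and 33 for day 7 and 23 and 17 for day 14 in untreated, and 8 were higher at all 3 days. With a floor of 200 reads they were 13 and 6 at day 3, 16 and 36 at day 7, and 15 and 11 at day 14. Within arms that floor gave 1 and 2 for day 7 and 6 higher for day 14 in FK506, 40 and 10 for day 7 and 5 and 3 for day 14 in untreated, and 2 higher at all 3 days. A prior count of 10 gave 1 higher for day 7 against day 3 in FK506 and 2 higher at all 3 days. With the top 3 miRNAs left out before scaling, 50 were higher at day 7 in FK506. In the time courses that setting gave 3 lower for day 7 in FK506, 49 lower for day 7 in untreated and 5 higher for day 14 in untreated. With days 3 and 14 only, 5 were lower at both. Other counts stayed within 1.5 times, including those without miR-3107 entries and without the nervous-system lists.

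For FK506 across days, edgeR's 0 calls became 5 with DESeq2, 1 with limma, 4 with no filter, 1 with at least 50 reads in 3 libraries, 2 with no day term, 4 with a robust prior and 3 without the FK506 day 14 library, and ranged from 0 to 4 with each day left out. Its 17 miRNAs under an unadjusted 0.05 became 4 to 32 over the 13 alternatives. The 4 calls without day 14 were miR-486-5p, miR-3107-5p and miR-296-5p higher and miR-181a-5p lower. Day 7 against day 3 gave 1 call with DESeq2 and 9 with no filter. Day 14 against day 7 gave 2 with DESeq2, 6 with no filter, 1 with a robust prior and 5 without the FK506 day 14 library. Lists past the threshold for FK506 went from 1 to 0 with an estimated correlation, with fry and without the untreated day 7 library. For day 14 against day 7 they went from 1 to 0 in the same 3 settings, and for day 14 against day 3 from 0 to 1, the liver list, without the untreated day 7 library. A day could not be left out of a contrast that uses it. Day as a term pairs the libraries in the fit.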

Other observations

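The tests and single miRNAs in this part were chosen after the data were seen.

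Tissue miRNAs of serum other than the erythroid ones were uneven. The liver miRNA miR-122-5p had 30, 26 and 1 reads in FK506 at days 3, 7 and 14, and 5, 0 and 60 in untreated serum, while miR-192-5p, made in liver and gut, had 837 to 8363. In muscle miRNAs, miR-133a-3p had 370 to 2138 reads per library, whereas miR-1a-3p, encoded beside it, had 0 to 2 and miR-206-3p 0 to 1. The myeloid miRNA miR-223-3p had 6 to 67 reads. Among red cell miRNAs, miR-451a had 523 to 4012 reads and miR-16-5p 2098 to 16659, against at least 2302676 for miR-486-5p.

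Per-day FK506 effects of the 93 miRNAs compared at every day correlated across miRNAs at Pearson 0.373 between days 3 and 7, 0.400 between days 3 and 14 and 0.265 between days 7 and 14. The miRNAs are not independent replicates, and the 3 pairs share no library.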
